A study of Mus musculus with 6 samples.

How the data were processed

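RNA was measured by total RNA sequencing of sorted LSK cells in 4 libraries, 1 each of young WT, young KO, old WT and old KO, made from 100 ng of total RNA per the labels' protocols with a total RNA library kit. The 2 samples of whole genome bisulfite sequencing were not analysed here. Groups, ages and genotypes were taken from the sample titles and labels.

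The deposited files give 1 FPKM per gene (fragments per kilobase of transcript, scaled to the total of the library), with a gene identifier, symbol, description and locus, per the file headers. The submitters' processing notes name the mouse build mm10 (GRCm38) and the tools CASAVA, FastQC, Trimmomatic, HISAT2 2.0.4 and StringTie 1.3.0, with no role or order. Whether strand was used in counting is not given in the sources used here, so genes that overlap on opposite strands may share reads. Each file lists only genes with an FPKM of 0.5 or more, which was seen in the values. A gene that a file does not list was set to 0.5, so that a fold against it is a lower bound. That choice was made after the data were examined, and unlisted genes at 0 are among the alternatives. Of 14468 gene identifiers, 14382 were found in a table of identifiers and symbols, and 18 symbols that had been turned into dates were restored from it. Values were summed over the 13 symbols with more than 1 row, giving 14455 symbols, of which 12152 were listed in all 4 libraries.

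The libraries were scaled by median-of-ratios factors over 10935 genes with an FPKM of 1 or more in all 4. The factors were 0.940 for young WT, 1.02 for young KO, 1.02 for old WT and 1.02 for old KO. Values in the text are scaled FPKM. Differences are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene was measured in a comparison when its scaled value was 1 or more in at least 1 of the 2 libraries and counted as 2-fold higher or lower when the difference reached 1. With 1 library per group there is no spread between replicates, and no p-value or SD is given.

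Depth was estimated from the spacing of low values. FPKM times locus length of genes shorter than 1500 bp lay within 0.02 steps of a whole multiple of 1 step for 61.7% and 61.3% of such values in the young and 69.1% and 72.8% in the old libraries, where chance gives 4%. For a length of 1 kb an FPKM of 1 then corresponds to 9.58, 9.04, 17.9 and 18.1 counted units in young WT, young KO, old WT and old KO. In the young libraries nearly all values were even multiples of a finer step (1.72% and 1.12% odd), in the old ones they were not (57.6% and 57.1% odd), so the values of the young and old libraries were spaced differently. The finer step was 0.0522, 0.0553, 0.0560 and 0.0554 FPKM times kb in young WT, young KO, old WT and old KO. A counted unit was taken as 2 finer steps in young and 1 in old libraries. The gap in units rests on that choice, and whether depth itself differed was not settled. The 2 predicted genes Gm26917 and Gm42418 held 18.3%, 25.5%, 12.4% and 17.8% of the summed FPKM of young WT, young KO, old WT and old KO. Counting errors do not cover duplicate reads.

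Before the data were examined, 29 gene lists with 1047 entries were fixed, of blood lineages and other cell types the sort could hold, cell cycle, stress, interferon, chromatin and control genes, and 966 entries were found in the files. Some genes are in more than 1 list. A list is described by the median difference of its measured members and by the percentile of that median among 10000 random lists of the same size, matched in 20 bins of mean expression. It is said to stand apart below percentile 2.5 or above 97.5. With 29 lists a few would pass by chance even if genes varied singly, as the random lists assume. Members of a list can vary together, so more may stand apart between any 2 libraries. How many would do so cannot be measured with 1 library per group.

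Genes were named by a rule fixed before the data were examined: Setd2; the 10 largest rises and 10 largest falls of each KO comparison at a value of 5 or more; up to 10 genes changed by 2-fold in one direction at both ages; up to 4 members with the largest change of each list described; 11 fixed genes of stem and progenitor cells, of which Nupr1 was listed in no library; and the 5 largest rises and falls of the age comparisons. Predicted and clone-named genes, pseudogenes, small RNAs, mitochondrial genes and antigen receptor segments, meaning those of immunoglobulins and T cell receptors, were left out of the ranked parts. Named long non-coding RNAs such as Xist were kept. The genes used for sorting, the sex-linked genes other than Xist and Eif2s3y, Gm20634, 20 plasma cell markers, Elane in the plot of genes, Hba-a2, Alas2 and Lyz2 were chosen after the data were seen. Some genes that the rule names are not reported here.

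The steps were tested on simulated libraries of the young comparison with 200 changed genes, at 2 kb of exon per gene. The first run took the depth of the old libraries, 18 counted units per FPKM and kb, and the test was then repeated at 9, that of the young ones. At 9 units 0% of the changed genes were called at a simulated 1.5-fold change, 24.5% at 2-fold, where the pseudocount keeps the difference under 1, 99.5% at 3-fold and 100% at 4-fold. At 18 units 21% were called at 2-fold and 100% at 3-fold. In the 2-fold run at 9 units 0 of 12342 unchanged genes were called. The simulation held counting error alone, so it gives no rate of false calls between real libraries. Its changed genes had a mean of 5 or more, so it does not show the recovery of lower genes. Alternatives tried were a pseudocount of 0.1 or 5, no minimum value or a minimum of 5, no scaling or upper-quartile scaling, the highest row of each symbol, protein-coding genes only, and a 4-fold threshold, and after the data were seen unlisted genes at 0, leaving out antigen receptor segments, only genes listed in all 4 libraries, leaving out plasma cell, neutrophil and immunoglobulin genes, and young WT as the control of old KO. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.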

Results

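RNA was measured in LSK cells, the Lin- Sca-1+ c-Kit+ fraction of mouse bone marrow that holds the hematopoietic stem cells and the earliest multipotent progenitors. The cells came from C57BL/6 mice with an inducible deletion of Setd2 (KO) and from wild-type mice (WT). Setd2 encodes the methyltransferase that places 3 methyl groups on lysine 36 of histone H3. Cells were taken 4 weeks (young) or 8 months (old) after injection of pI-pC, the double-stranded RNA that switched on the deletion. Each of the 4 groups had 1 total RNA library. No difference therefore has a replicate check or a p-value, and all of them describe these libraries alone. The files listed 13312 genes for young WT, 13182 for young KO, 13327 for old WT and 13204 for old KO, each at an FPKM of 0.5 or more. From the spacing of low values, a transcript of 2 kb at an FPKM of 5 corresponded to 95.8 counted units in young WT, 90.4 in young KO, 179 in old WT and 181 in old KO. That gives a counting error of 10.2%, 10.5%, 7.48% and 7.44% in the same order, which covers counting alone. The lower error of the old libraries rests on how a unit was taken, as 2 finer steps in young and 1 in old libraries. The 2 bisulfite sequencing samples of young WT and KO cells were not analysed here.

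Setd2 itself (ENSMUSG00000044791, chromosome 9, 110532597 to 110618633, mm10) had a scaled FPKM of 14.1 in young WT and 12.4 in young KO, and of 15.3 in old WT and 15.5 in old KO. The gene-level value therefore barely differed between genotypes, by -0.18 on the log2 scale in young and 0.02 in old cells. A conditional allele can leave RNA outside the deleted exons, so this value neither checks the labels nor contradicts them. Of the genes used for sorting, Kit, the receptor of stem cell factor, stood at 61.0, 52.9, 44.5 and 41.1 in young WT, young KO, old WT and old KO, and Ly6a, which encodes Sca-1, at 4.86, 3.17, 8.80 and 4.18. Ly6a lay far below Kit in all 4 libraries. The purity of the sort was not tested in any library. Differences of lineage genes may therefore reflect the mix of sorted cells, at either age. The young and old pairs of libraries also differed in sex-linked genes. Xist, the RNA of the inactive X chromosome, was not listed in either young library and stood at 291 and 279 in old WT and KO, whereas the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed only in the young libraries, with Eif2s3y at 9.91 and 11.9.

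The first comparison asked what loss of Setd2 changed in young cells. Genes of red cell development were higher in young KO cells: all 39 measured members of the erythroid list lay above 0, 10 of them by 2-fold or more, and the list median was 0.70 on the log2 scale. The middle 95% of random lists ran from -0.08 to 0.09. Among the erythroid genes were the transcription factors Klf1, at 12.3 in WT and 28.7 in KO, and Gata1, at 15.4 and 25.0. The blood group genes Rhd, at 5.83 and 21.4, and Rhag, at 8.06 and 22.8, were higher too, as were the biliverdin reductase Blvrb, at 8.40 and 22.5, and the beta globin Hbb-bs, at 46.8 and 220. A second beta globin gene, Hbb-bt, differed less, at 52.2 and 80.7. Mitosis genes were slightly higher, with 36 of 40 above 0 and a median of 0.26. Cks2 stood at 19.4 and 30.0 and Hjurp, which loads histones at centromeres, at 30.2 and 43.8. No mitosis gene reached 2-fold.

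Several myeloid and immune groups were lower in the same young KO library, each by less than 2-fold for nearly every member. The median was -0.19 over 33 granulocyte-monocyte progenitor genes, of which 25 lay below 0. It was -0.36 over the 11 measured neutrophil genes, -0.22 over 17 monocyte and macrophage genes, -0.28 over 21 dendritic cell and MHC class II genes and -0.12 over 26 lymphoid priming genes. Csf1r, the receptor of macrophage colony-stimulating factor, stood at 8.91 in WT and 4.92 in KO, and Cebpd at 8.40 and 3.54. The lymphoid priming genes went both ways, with 15 below and 11 above 0 and a mean of 0.03, and theirs was the only list standing apart in a KO comparison whose mean and median differed in sign. Dntt, which adds nucleotides during antigen receptor rearrangement, was lower, at 110 and 61.9, while Ighm (66.3, 138), Ets1 (1.74, 4.24) and Rag1 (1.40, 2.70) were higher. Immediate early and heat shock genes had a median of -0.26 over 32 genes, with Egr1 at 10.6 and 4.74 and Klf2 at 17.1 and 8.06. The heat shock genes Hsph1 and Hspa1b went the other way, with Hsph1 at 5.74 and 15.8 and Hspa1b not listed in WT and at 5.51 in KO. Interferon-stimulated genes had a median of -0.11 with none of 40 changed by 2-fold. That of p53 target genes was 0.13 over 28 genes, again with none changed by 2-fold. Mitochondrially encoded genes had a median of -0.35 over 13 genes, led by mt-Nd4l, which stood at 126 in WT and was not listed in KO. Genes of the stem cell signature had a median of -0.10 at percentile 2.54 of random lists. This is at the limit of standing apart, which it passed with a pseudocount of 0.1 and under 3 restrictions to fewer genes that were chosen after the data were seen. Members did not move as one, with Hlf, a transcription factor of stem cells, at 11.1 and 14.1, Mecom at 2.46 and 3.14, and Gata3 at 1.16 and 3.08. Myc stood at 10.8 and 10.2, Flt3 at 47.7 and 38.6 and Cd34 at 60.4 and 53.2.

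In all, 126 genes were at least 2-fold higher and 87 at least 2-fold lower in young KO cells among 12409 measured. Of these, 40 of the higher and 19 of the lower were immunoglobulin segments, and 4 and 1 were T cell receptor segments. Without predicted, small RNA and mitochondrial genes as well, 65 were higher and 51 lower. The largest positive differences, with these classes aside, were Hbb-bs, the histone variant gene H2afz (5.36 in WT, 27.8 in KO), Hspa1b, the bone collagen gene Col1a1 (not listed in WT, 5.48 in KO), Cited4 (1.73, 8.67), Rhd, Tspan2 (1.47, 7.05), Zfx (2.23, 9.38), Scin (1.64, 7.07) and Rprd1b (2.83, 10.5). The largest negative differences were the histone gene Hist2h2aa1 (617, 54.1), Hnrnpa3 (22, 1.89), Ube2l3 (13.1, 1.28), Hist1h2be (9.90, 1.48), Bloc1s1 (6.5, 0.807), Tmem127 (13, 2.61), Nkx2-3 (6.74, 1.49), Cds2 (15.4, 4.83), Zbtb20 (6.89, 1.84) and Nfe2l1 (7.50, 2.09). Hist2h2aa1 overlaps the predicted gene Gm20634, which stood at 5.48 in WT and 185 in KO, and reads were not separated between them here. Without scaling, which lowered the median of all genes to -0.10, the balance turned to 99 higher and 118 lower.

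The second comparison asked the same in old cells. Myeloid genes were higher in old KO cells: 31 of 33 granulocyte-monocyte progenitor genes lay above 0, 7 of them by 2-fold, with a median of 0.69 against a range of -0.05 to 0.14 for random lists. The transcription factor Irf8 stood at 11.7 in WT and 37.5 in KO, Csf1r at 8.31 and 29.1, the coagulation factor gene F13a1 at 35.2 and 171, and Ly6c2, a surface protein of monocytes, at 9.62 and 34.5. Of 23 measured neutrophil genes, 14 were 2-fold higher and the median was 1.26. Among them were the granule genes Camp (2.86, 40.8), Ltf (1.28, 12.9), Ngp (3.45, 26.1) and Mmp8 (0.976, 9.43), Retnlg (2.06, 40.4), Chil3 (2.64, 39.5) and the calprotectin subunits S100a8 (19.5, 123) and S100a9 (9.24, 68.6). Monocyte and macrophage genes had a median of 0.74, with 8 of 19 at least 2-fold higher, including Ms4a6c (14.9, 76.6), Ly86 (7.55, 32.1) and Ccr2 (1.64, 8.03). Another 1, the complement gene C1qa (3.29, 0.924), was 2-fold lower. Ccr2 stood at 9.88 in young WT and 6.92 in young KO, so for it the old WT value was the low one.

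Interferon-stimulated genes were higher with them, 41 of 44 above 0 and 9 by 2-fold, at a median of 0.60. Ifi27l2a stood at 4.68 in old WT and 23.9 in old KO, the antiviral enzyme gene Oas2 at 1.15 and 4.77, Rtp4 at 4.28 and 13, and Isg15 was not listed in WT and stood at 5.08 in KO. Immediate early and heat shock genes had a median of 0.34, with Atf3 at 5.31 and 21.0, Ppp1r15a at 12.1 and 33.9, Hspa1b at 2.07 and 8.19 and Hspa1a at 2.96 and 8.44. Smaller shifts in the same direction stood apart for 64 replication-dependent histone genes, at a median of 0.34, and for 31 lymphoid priming genes, at 0.31. They also did for 22 dendritic cell and MHC class II genes, at 0.21, for 40 mitosis genes, at 0.20, for 77 cytoplasmic ribosomal protein genes, at 0.14, and for 19 T and NK cell genes, at 0.38. The last no longer stood apart over genes listed in all 4 libraries, where its median was 0.19. The dendritic cell and MHC class II list went both ways, 12 genes above 0 and 10 below, with Irf4 at 33.9 and 4.41. In the lymphoid priming list 21 were above 0 and 10 below, with Jchain among the lower.

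Erythroid genes were lower in old KO cells, opposite to young cells, with 28 of 37 below 0, 5 of them by 2-fold, 3 genes 2-fold higher, and a median of -0.48. Car1, a carbonic anhydrase of early red cell precursors, stood at 123 in WT and 52.6 in KO, the erythropoietin receptor gene Epor at 16.5 and 6.55, Icam4 at 7.73 and 2.80, Gata1 at 17.3 and 8.50 and Klf1 at 20.6 and 12.4. All 6 measured late genes, the globins, Slc4a1 and Alas2, went against their list, with a median of 0.98. Hbb-bs stood at 12.2 and 28.1, Hbb-bt at 5.51 and 13.1 and Hba-a2, the last of the 3 that were 2-fold higher, at 1.58 and 4.32. Genes of the stem cell signature had a median of -0.18, with 26 of 35 below 0. Hlf stood at 14.7 and 6.2 and Mecom at 2.5 and 1.80, whereas Ifitm1, an interferon-induced gene of the same list, stood at 74.1 and 152. Megakaryocyte and platelet genes had a median of -0.29 over 27 genes, with Vwf at 5.08 and 2.35 and Pf4 at 10.1 and 5.41. Mast cell, basophil and eosinophil genes had a median of -0.42, with 17 of 19 below 0, including the basophil protease gene Prss34 at 50.2 and 11.0 and the eosinophil granule gene Prg2 at 175 and 65.8. The stromal and endothelial median was -0.39 over 10 genes and that of Hoxa and Hoxb genes -0.34 over 10 genes. Neither stood apart over genes listed in all 4 libraries, with medians of -0.24 and -0.22. The median of 40 S phase genes was -0.07, with Fen1 at 18.7 and 7.12.

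In all, 204 genes were at least 2-fold higher and 332 at least 2-fold lower in old KO cells among 12478 measured, and 184 of the 332 were immunoglobulin segments. Immunoglobulin segments held 26.7% of the summed FPKM of old WT, 4.63% of old KO, and 0.617% and 0.861% of young WT and KO. The largest negative differences, predicted, small RNA, mitochondrial and antigen receptor genes aside, included genes of plasma cells, which secrete antibody. They were Jchain, the joining chain of IgA and IgM (1891 in WT, 141 in KO), the immunoglobulin chaperone gene Mzb1 (106, 11.2), the transcription factor Irf4 (33.9, 4.41), Ccr10 (8.16, not listed), Tnfrsf17, which encodes the survival receptor BCMA (11.4, 1.11), Fam46c (34.1, 5.40), St6gal1 (14.4, 1.84), Derl3 (20.4, 3.05), Cd79a (23.4, 3.84) and Cacna1h (7.98, 0.972). The largest positive differences, with the same classes aside, were Retnlg, Chil3, Camp, Ifitm6 (2.00, 21.8), S100a9, Ltf, Ngp, S100a8, the zinc finger gene Zfp422 (1.80, 15.5) and Mmp8. Zfp422 stood at 17.8 in young WT and 17.4 in young KO, so for it the old WT value was the low one. The B cell list had a median of -0.63 over 18 genes, of which 7 were 2-fold lower, and -0.17, no longer apart, without antigen receptor segments. Without those segments 193 genes were higher and 148 lower in old KO. Without plasma cell, neutrophil and immunoglobulin genes the counts were 179 and 134, and both restrictions were chosen after the data were seen.

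**Figure D1:**
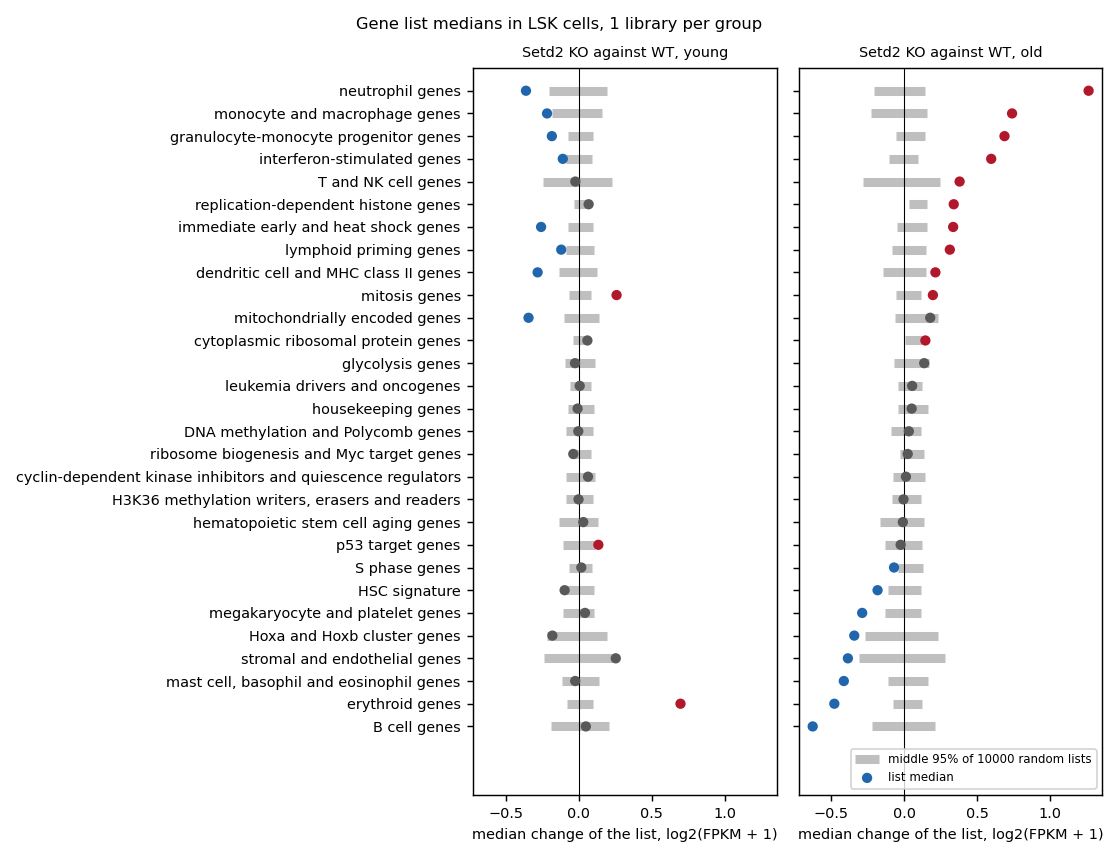
Median change of each gene list in Setd2 KO against WT (horizontal axis, difference on the log2(FPKM + 1) scale) in young (left) and old (right) LSK cells, 1 library per group. Points are list medians, red above and blue below the middle 95% of 10000 random lists of matched expression (grey bars) and dark grey within it. Erythroid genes lie at 0.70 in young and -0.48 in old cells, and neutrophil genes at -0.36 and 1.26.

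Lists of H3 lysine 36 methylation genes, DNA methylation and Polycomb genes, ribosome biogenesis and Myc target genes, glycolysis genes, cyclin-dependent kinase inhibitors and quiescence regulators, hematopoietic stem cell aging genes, housekeeping genes and leukemia drivers stood apart at neither age. In that order their medians were -0.00, -0.00, -0.04, -0.03, 0.06, 0.03, -0.01 and 0.01 in young cells and -0.01, 0.03, 0.02, 0.14, 0.01, -0.01, 0.05 and 0.05 in old cells. The glycolysis list in old cells passed the limit unscaled, at 0.17, and with upper-quartile scaling, at 0.18. Single members of these lists did differ. Cdkn2c, an inhibitor of the G1 kinases, stood at 7.09, 4.19, 12.4 and 4.02 in young WT, young KO, old WT and old KO, the polycomb gene Suz12 at 23.4, 23.4, 23.7 and 13, and the ubiquitin ligase gene Cbl at 23.5, 23.4, 18.2 and 8.51. In young cells the medians of S phase genes (0.02), megakaryocyte and platelet genes (0.04), B cell genes (0.05), T and NK cell genes (-0.02), histone genes (0.07) and ribosomal protein genes (0.06) lay within the range of random lists, and each changed sign under no scaling or upper-quartile scaling. So did those of mast cell, basophil and eosinophil genes, at -0.03, and of Hoxa and Hoxb genes, at -0.18, which kept their sign. The B cell list came to stand apart as lower, at -0.28, without plasma cell, neutrophil and immunoglobulin genes. Histone genes lay so near the limit that a pseudocount of 5 made them stand apart. Stromal and endothelial genes, at 0.25 with Col1a1 as the largest change, stood apart under both other scalings and not over genes listed in all 4 libraries, where their median was -0.08. In old cells the medians of p53 target genes, at -0.03, and mitochondrially encoded genes, at 0.18, lay within the range of random lists.

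The 2-fold changes at both ages overlapped more than independent lists would, in the same and in opposite directions. Among 11873 genes measured in both comparisons, 12 were 2-fold higher in KO at both ages, where independent lists would share 1.67. Another 28 were 2-fold lower at both, where they would share 1.85. The largest overlap was of 41 genes higher in young KO and lower in old KO, where they would share 2.69, and 2 genes were lower in young and higher in old KO, where they would share 1.15. Without predicted, small RNA, mitochondrial and antigen receptor genes the counts in the same order were 6 against 0.763, 9 against 0.506, 9 against 0.638 and 1 against 0.605. The changes were nearly uncorrelated across genes, with a Pearson r of -0.02 and a Spearman rho of 0.02, and genes are not independent replicates. At a value of 5 or more and without those classes, 4 genes were higher at both ages. Trim25, a ubiquitin ligase of antiviral signalling, stood at 12.5 in WT and 31 in KO in young cells and at 13 and 32 in old cells. Isyna1, which makes inositol phosphate, stood at 51.4 and 117 and at 49.2 and 101, and Hspa1b and Hbb-bs were the others. Lower at both ages, with the same limits, were the homeobox gene Nkx2-3 (6.74 to 1.49 in young, 7.18 to 2.30 in old cells), Ptk7 (9.90 to 4.11, 5.17 to 1.59), Ltbp3, a carrier of latent TGF-beta (14.6 to 6.21, 11.0 to 4.67), Ppp1cc (5.64 to 2.21, 5.08 to 1.75), Tmem127 (13 to 2.61, 13.1 to 2.57) and Hnrnpa3 (22 to 1.89, 19.4 to 3.69).

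**Figure D2:**
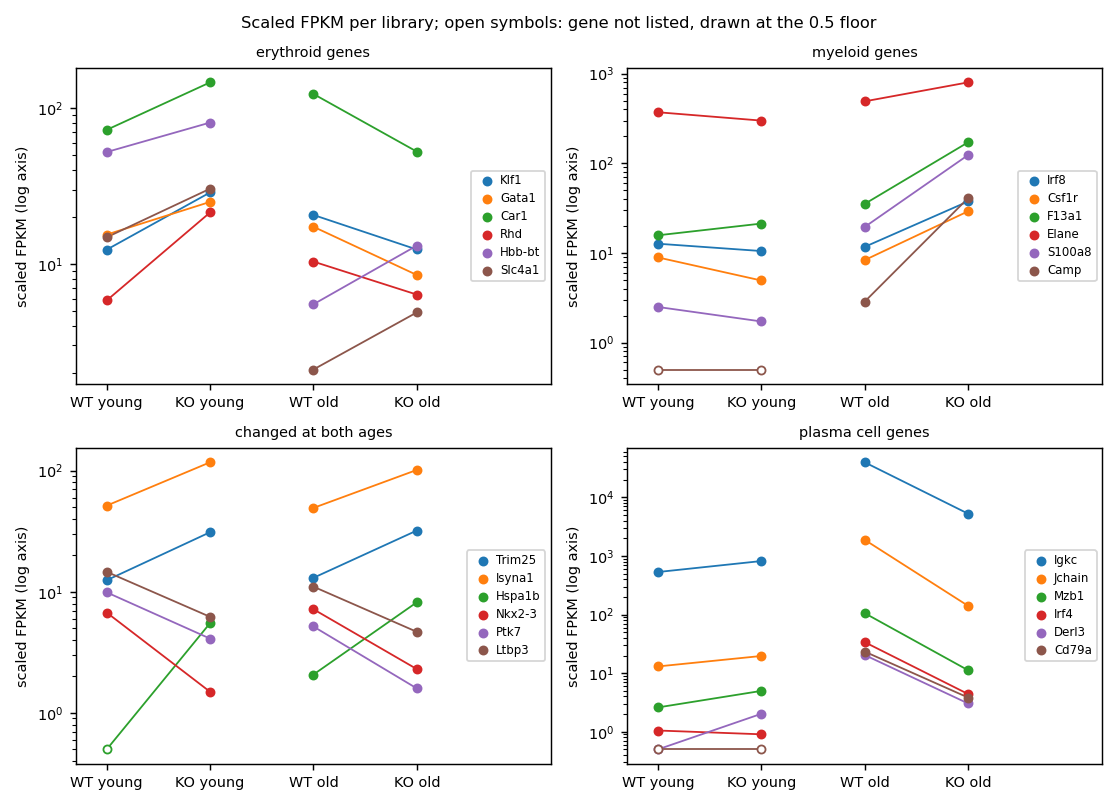
Scaled FPKM (vertical log axis) of 24 genes in the 4 libraries, 1 point per library, with lines joining WT and KO of one age and open points for genes not listed, drawn at 0.5. Klf1 goes from 12.3 to 28.7 in young and from 20.6 to 12.4 in old cells, Trim25 is higher in KO at both ages (12.5 to 31 and 13 to 32), and Jchain stands at 1891 in old WT and 141 in old KO.

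The remaining comparisons set old against young cells of each genotype. They join age with sex and with time after pI-pC, 4 weeks against 8 months. The values of the young and old libraries were also spaced differently. Age, time after pI-pC, sex and library preparation therefore cannot be told apart there. In WT cells 531 genes were 2-fold higher and 167 lower in old among 12569 measured, and 205 of the 531 were immunoglobulin segments. In KO cells 620 were higher and 281 lower among 12534, and 111 of the 620 were immunoglobulin segments. Of the genes measured in both, 268 were higher in old cells of both genotypes, where independent lists would share 23.3, and 63 were lower, where they would share 3.80. Immediate early and heat shock genes differed most among the lists in both genotypes, with medians of 1.37 in WT, where 24 of 34 were 2-fold higher, and 1.95 in KO, where 26 of 34 were. Klf2 stood at 17.1 and 105 in young and old WT and at 8.06 and 163 in young and old KO. Ribosomal protein genes had medians of 0.49 and 0.54, and mast cell, basophil and eosinophil genes of -0.77 and -1.0. Prss34 stood at 279 and 50.2 in young and old WT and at 274 and 11 in young and old KO. The genotypes parted for other lists, a difference that was not tested. The erythroid median was -1.25 in KO, where 27 of 39 genes were 2-fold lower. In WT it was 0.15 with a mean of -0.20, and 6 of 38 genes were 2-fold lower and 0 higher. The granulocyte-monocyte progenitor median was -0.05 in WT and 0.81 in KO. With the same classes aside, the largest positive differences in WT were Xist, Jchain, Mzb1, Irf4 and Cd79a and the largest negative ones Hbb-bt (52.2, 5.51), Eif2s3y, Zfp422 (17.8, 1.80), Prss34 and Ccr1 (13, 1.69). In KO the positive ones were Xist, S100a9, S100a8, Camp and Klf2 and the negative ones Prss34, Eif2s3y, Hbb-bs, Hbb-bt and Slc4a1, the red cell anion exchanger (30.4, 4.89).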

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

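The tests of scaling, red cell RNA, sex or library preparation, plasma cells, neutrophils and counting error were chosen after the results were seen, and that of overlapping loci before. With 1 library per group, none of the differences between ages was tested. They were picked because a change went in opposite directions in young and old cells. Of the 20 plasma cell markers used, 14 were listed in a young library too, and of the 30 neutrophil genes 11 were measured in the young comparison.

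Erythroid genes were higher in young KO and lower in old KO, with list medians of 0.70 and -0.48, a difference of -1.18 on the log2 scale. A factor per library moves genes of like expression alike, and the medians lay at least 0.41 outside the range of random lists matched in expression. The list was flagged for lying outside that range, so this reading could not have favoured scaling, and no conclusion is drawn from it. Neither median changed sign without scaling or with upper-quartile scaling. Without scaling the median of all genes moved only to -0.10 in young KO, too little to reverse medians of this size. Nothing is concluded from that either. Carried-over RNA of mature red cells is argued against for young KO: the 32 erythroid genes other than globins and other late genes had a median of 0.73, against 0.63 for the 7 late ones. Red cell precursors among the sorted cells would carry both parts of the list, so this comparison does not address them. In old KO the parts separated, with the 6 measured late genes all higher, at a median of 0.98, and the other 31 at -0.58. Whether sex, library preparation or time after pI-pC, in place of age, set the opposite directions cannot be told apart here. Old cells were taken 8 months and young cells 4 weeks after pI-pC, and 4 Y-linked genes were listed only in young. The libraries also differed up to 2.00-fold in counted units, as these were taken here. An effect of Setd2 loss that changes with age or with time since the deletion remains open as a hypothesis.

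Genes of mature blood cells were high in the old libraries, plasma cell genes most in WT and neutrophil genes most in KO, in cells whose sort should remove them. Each set was also higher in old than in young cells of the other genotype. The neutrophil median was 0.63 in old against young WT, with 6 of 17 genes 2-fold higher. Immunoglobulin segments held 4.63% of the summed FPKM of old KO and 0.861% of young KO. The neutrophil median in old KO lay 1.12 outside the range of matched random lists. This list was flagged by that range too, so no conclusion on scaling is drawn from it. Plasma cells among the sorted old WT cells may account for the plasma cell genes there. Of 18 such genes, 66.7% (12) had an old KO to WT ratio of excess over the young libraries within 2-fold of the median of 0.111. Igkc stood at 39779 and 5284, Igha at 5796 and 480 and Jchain at 1891 and 141 in old WT and KO, but Ighm, at 490 and 649, did not follow. For neutrophil genes the ratio was taken the other way, old WT to KO, and 58.8% of 17 lay within 2-fold of their own median of 0.115. S100a8 stood at 19.5 in old WT and 123 in old KO, while Lyz2, at 72.5 and 176, did not follow. This leaves mature neutrophils open. Whether they also account for the granulocyte-monocyte progenitor genes cannot be told apart from a myeloid shift of the old KO cells, which remains an untested hypothesis: leaving out neutrophil and monocyte list genes took away only 1 of 33 genes, with a median of 0.65 over the rest.

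Some single genes with large changes in young KO changed the opposite way in old KO. H2afz stood at 5.36, 27.8, 14.8 and 5.58 and Zfx at 2.23, 9.38, 8.50 and 2.19 in young WT, young KO, old WT and old KO. At a value of 5 or more, predicted, small RNA, mitochondrial and antigen receptor genes aside, 79 genes changed by 2-fold. Counting error as the whole cause is argued against, since it would give 17.3 of them at 0.5 kb of exon per gene and 0.336 at 1 kb. Duplicate reads were not covered. Reads shared with overlapping listed loci are argued against as the whole cause, since only 21 of the 79 (26.6%) overlapped another listed locus. Matched sets of unchanged genes had a median of 26.6% and a range of 19.0% to 35.4%. The share lay neither above that range nor below that median, so the planned comparison could not tell. Among the 79, 1 gene overlapped a gene with an opposite 2-fold change, and for single overlapping genes shared reads remain open. Sharing with near-identical copies elsewhere and differences in transcript assembly were not tested.

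Other opposite changes are given as values. The old minus young difference was -3.44 for H2afz, -3.26 for Zfx, -2.21 for Car1, -3.45 for Derl3 and 4.00 for Ifitm6. For list medians it was 0.87 for granulocyte-monocyte progenitor genes, 1.63 for neutrophil genes, 0.96 for monocyte and macrophage genes, 0.50 for dendritic cell and MHC class II genes, 0.43 for lymphoid priming genes, 0.71 for interferon-stimulated genes and 0.59 for immediate early and heat shock genes.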

How the results depend on the processing

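Alternatives chosen after the data were seen are named as such. No gene list that stood apart and no named gene past 2-fold changed sign under an alternative it was recomputed in. For the genes this outcome was nearly fixed beforehand. A pseudocount keeps the sign of a difference, and the library factors lay too close together to reverse a 2-fold change. Of 520 recomputed list medians 442 moved by less than 1 SD of random lists, and of 1788 recomputed gene changes 1664 moved by less than 1.5-fold. These totals pool settings that differ widely. Of 58 list medians, 26 moved further without scaling, 22 with a pseudocount of 5 and 13 with 0.1. Of 298 gene changes, 65 moved further with a pseudocount of 5 and 38 with 0.1. Both other scalings and the highest row of each symbol moved no gene that far. The lists that ceased to stand apart, all in old KO, were the B cell list without antigen receptor segments (-0.17) and without plasma cell, neutrophil and immunoglobulin genes (-0.16), and the T and NK cell (0.19), stromal (-0.24) and Hox (-0.22) lists over genes listed in all 4 libraries; the cause was not tested. Leaving out the minimum value changed no count of genes, since 2 values between 0.5 and 1 cannot differ by 2-fold with a pseudocount of 1, and taking the highest row of each symbol changed none either. Counts below are given as higher and lower. The gene numbers depended on the pseudocount, as its construction implies. With a pseudocount of 0.1 they were 361 and 273 in young KO, 433 and 639 in old KO, 855 and 453 in old WT against young, 983 and 680 in old KO against young, and 33 and 64 at both ages. With a pseudocount of 5 they were 32 and 12, 54 and 207, 308 and 48, 270 and 52, and 4 and 8 in the same order. A 4-fold threshold left 18 and 8, 27 and 182, 240 and 22, 136 and 22, and 2 and 4. A minimum value of 5, which tests fewer genes, gave 81 and 44 in young KO, 123 higher in old KO, 103 lower in old WT, 184 lower in old KO against young, and 7 and 16 at both ages. Protein-coding genes only, again fewer genes, gave 59 and 48 in young KO, 145 and 119 in old KO, 240 and 77 in old WT, 376 and 144 in old KO against young, and 6 and 9 at both ages. The share of higher genes in old KO thereby turned from 38.1% to 54.9%. No scaling moved none of the counts by over 1.5 times but turned the share of higher genes in young KO from 59.2% to 45.6%, because the median of all genes moved to -0.10 on the log2 scale. The share in old WT against young went from 76.1% to 67.0% unscaled. Of the settings chosen after the data were seen, unlisted genes at 0 gave 228 and 178 in young KO, 332 higher in old KO, 298 lower in old WT, 431 lower in old KO against young, and 19 and 44 at both ages. Without antigen receptor segments 82 genes were higher in young KO, 148 lower in old KO, 323 higher in old WT and 10 lower at both ages. Without plasma cell, neutrophil and immunoglobulin genes these numbers were 80, 134, 303 and 10, and 5 instead of 3 lists stood apart as higher in young KO with stromal and histone genes, both near the limit, added. Young WT as the control of old KO gave 605 and 216. Files with a second unit (TPM) were not used here, so that alternative was not run. With units taken as above, 2 kb at an FPKM of 1 carries a counting error of 22.9% and 23.5% in young WT and KO and 16.7% and 16.6% in old WT and KO. The larger error of the young libraries rests on that choice of unit.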

Other observations

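Some changes ran across genotype and age in ways the comparisons above do not show. In old WT cells the kappa and alpha constant region genes were abundant, with Igkc at 39779 and Igha at 5796, while Ighm, the mu chain gene that early lymphoid progenitors also transcribe, stood at 66.3, 138, 490 and 649 in young WT, young KO, old WT and old KO. The lambda genes Iglc1 and Iglc2 stood at 1183 and 154 in old WT and at 150 and 7.17 in old KO. Among p53 target genes, Pmaip1, a promoter of cell death, stood at 0.742, 1.32, 4.67 and 19.3 in the same order, and Perp at 1.03, 2.61, 0.540 and 2.17. In old KO against WT 2 of the 29 measured p53 target genes were 2-fold higher, 1 was 2-fold lower, and 17 lay below 0. The cyclin gene Ccnd3 stood at 2.97 and 7.39 in young and at 2.35 and 4.65 in old WT and KO, while Ccne1 stood at 3.11 and 6.69 and at 6.46 and 4.54. Hoxa2 was not listed in either KO library and stood at 2.43 in young and 1.41 in old WT.

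The mitochondrial gene mt-Nd4l was listed in both WT libraries, at 126 and 62.2, and in neither KO library. How its reads were assigned is not given in the sources used here.

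A wider shared set, taken at 1.5-fold, held 35 genes higher and 58 lower in KO at both ages, predicted, small RNA, mitochondrial and antigen receptor genes aside. Independent lists would share 11.8 and 11.9. A targeted allele can carry sequence of another strain on its chromosome, and such a stretch may give changes shared by both ages. Of the 93 genes, 3 lay within 20 Mb of Setd2, 1.67 times the share of all measured genes, too few to tell. This test was planned before its result was seen. An effect of Setd2 loss that persists with age remains open as an untested hypothesis.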
